A study of Mus musculus with 12 samples.

How the data were processed

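RNA from the livers of vehicle-treated and bulaquine-treated mice was compared on 12 spotted 2-colour arrays, 4 at each of 6 h, 12 h and 24 h after treatment. Each array carried a drug sample in one dye and a vehicle sample in the other, and per the labels the drug was in Cy5 on the 2 arrays called F1 and F2 of a time point and in Cy3 on the 2 called R1 and R2. The labels leave open whether F1 and R1 share RNA, whether vehicle animals were shared between time points, and what dose was given. The p-values therefore measure the spread between arrays, which may be technical in part.

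Per the series' design text, slides were scanned with ImageQuant v5.0 and the spot intensities were extracted with ArrayVision v8.0. The intensity columns as deposited by the authors held foreground, local background and background-corrected intensity per channel for 23040 spots, together with ArrayVision's signal-to-noise score per channel, whose formula is not given in the sources used here. The corrected column equalled foreground minus background within 0.001, with 0 where the background was higher. The authors' deposited value table held 1 log2 ratio per array. Set against the scanner intensities it was log2(Cy5/Cy3) after an intensity-dependent normalization, with dye-swapped arrays left unturned, and it correlated at r of 0.998 to 1.000 across spots with ratios recomputed by loess. Its column medians ran from -0.01 to 0.04. Per the series' design text, that normalization was LOWESS and the log ratios came from Avadis v4.

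The depth of an array is given here by its signal over background. The median signal-to-noise score per array was 0.76 to 1.42 in Cy3 and 0.47 to 1.34 in Cy5, and 9.66% to 24.5% of spots per array stood at 0 in either channel. The highest share was on array F2 of 12 h. The number of arrays limits the precision, and the median standard error of a log2 ratio at 1 time point was 0.22.

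The values tested were the deposited corrected intensities, as the design fixed before the data were examined asked for files that are already corrected. Spots at 0 in either channel were set to missing, log2(Cy5/Cy3) was normalized by global loess within each array, and the 11749 probes measured on all 12 arrays were tested. The restriction to those probes, and the final choice of the corrected column over normexp, were settled after counts under normexp had been seen. Some spots had a background far above the foreground, with foreground minus background down to -2124200 units in Cy5. Whether this is why normexp gave other counts was not tested. Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 column per time point coded by dye orientation, a dye effect for each probe, and all 12 arrays in 1 fit, which left 8 residual degrees of freedom (9.78 after eBayes). Calls used a Benjamini-Hochberg adjusted p under 0.05. The dye effect itself passed for 3398 probes, 1816 brighter in Cy5 and 1582 brighter in Cy3.

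The spot numbers of the scanner files and of the value table did not pair with the probe numbers of the annotation table. Paired by number as deposited, spots of 1 gene showed no relation in mean log2 intensity (r = 0.005 over 7882 pairs of spots), and the Apoa1 spot stood at the 1.95th percentile of brightness. The spots form 48 blocks of 480. When the blocks were read as 12 rows by 4 columns, numbered down columns in the one file and along rows in the other, the same correlation was 0.12, and that of the dye effect rose from 0.006 to 0.21. The other orders of rows and columns lay between -0.02 and 0.02, and the highest of 1000 random block orders gave 0.046. Tested one at a time, 24 of the 48 blocks matched best at their renumbered place on intensity and 12 on the dye effect. Both layouts place 960 spots alike. The renumbered order was found after the data were seen, in a scan of 79296 spot orders (74824 distinct), scored on ranks of the brightness of probes of 1 gene and never on the drug ratio. On ranks it gave 0.142, where the highest of the other scanned orders gave 0.051 and the highest of 79296 random block orders 0.056. Gene names and gene list tests had first been computed with the deposited numbering and were then redone, with every rule for naming left as fixed before. Every gene name below rests on this inferred order. So do counts by symbol or annotation, such as those of globin probes. Counts of tested or called probes made without regard to names do not.

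The annotation table paired 15114 probes with 1 gene symbol and 206 with several, and left 7720 spots without one. Gene identifiers of 14956 symbols were found in a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols needed an update. Among the tested probes 7829 had 1 symbol, 138 several and 3782 none, for 5691 genes. Named genes at a time point were, among probes with 1 symbol, called and of 1 sign on all 4 arrays, up to 12 of the largest changes in each direction, with the probe of the smaller p for a gene. Up to 5 in each direction were named for each difference between time points, and up to 4 members of each gene list by the test over all 3 time points.

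The 33 gene lists, written before the data were examined, covered drug metabolism, stress responses, liver injury, heme and iron, liver metabolism and other cell types. Of their 1174 members 485 were measured at gene level, by the brightest probe of a gene, and the 25 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry stood beside it. Alternatives covered the background, the normalization, dim probes, the dye effect, dye-swap pairs as blocks or means, time points fitted alone, eBayes with trend, each array left out, the authors' log2 value table, thresholds and list tests. Those added after seeing the data were normexp with offset 50, 2 wider probe sets, loess by blocks of 480 spots and names as deposited. No copies of a probe were marked, so nothing was averaged.

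The procedure was tested on simulated data built on the 11749 probes. At 6 h it recovered 50.7% of probes changed 2-fold and 84.8% of those changed 4-fold, with 6 false calls. At 12 h the shares were 40.3% and 81.8%, and at 24 h 47.8% and 81.8%. Of probes changed 1.5-fold, 5.97% to 13.4% were recovered. A list of 20 members shifted by 0.5 was found at each time point, with 0 other lists called. The simulated noise was independent between probes and lists held random probes. The simulation therefore cannot show how the list test behaves where members of a list are correlated.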

Results

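Gene expression was measured in mouse liver after bulaquine, an antimalarial of the aminoquinoline class and a pro-drug of primaquine, against vehicle. The sample titles place the study under hepatotoxicity, so the question was which liver transcripts change in the hours after the drug. The 12 arrays fall into 3 groups of 4, taken 6 h, 12 h and 24 h after treatment, and each array set a drug sample against a vehicle sample with the dyes swapped on 2 of the 4. Of 23040 spots, 11749 were measured on every array. Values are log2 ratios of drug over vehicle with their standard error (SE) from limma, and n = 4 arrays at each time point.

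Gene names rest on an order of the array's blocks that was inferred from the data, because the deposited spot numbers did not pair with the annotation. Under the deposited numbering, the spot of the apolipoprotein gene Apoa1 stood at the 1.95th percentile of brightness and that of transthyretin (Ttr) at the 63.8th. With the blocks renumbered they stood at the 99.5th and the 98.9th, and 135 probes of ribosomal proteins moved from a median of the 57.6th to the 89.1st percentile.

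**Figure D1:**
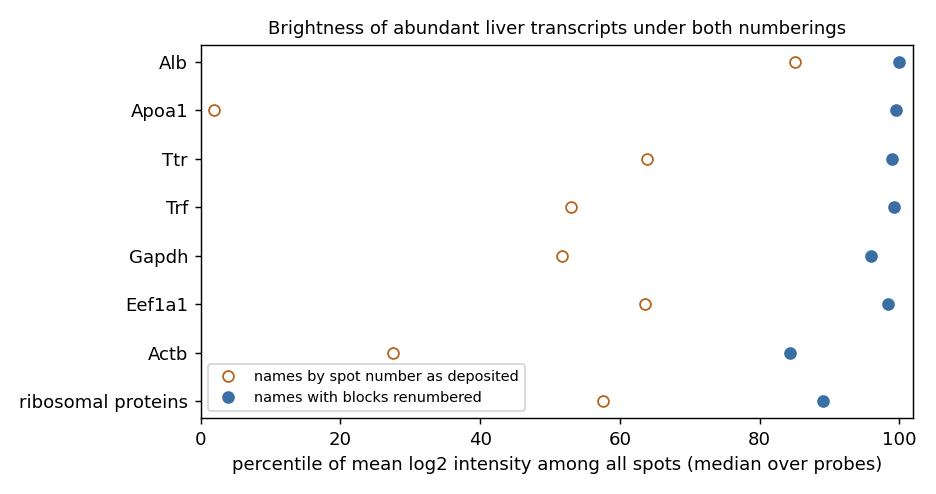
Median percentile of mean log2 intensity among all spots (horizontal axis, percent) for probes of abundant transcripts (vertical axis), named by the deposited spot number (open circles) or with the blocks renumbered (filled circles). All 8 rows lie higher after renumbering, with albumin (Alb) moving from 85.1 to 99.98.

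At 6 h the metallothioneins, small metal-binding proteins, were the most clearly changed genes. Mt2 was 4.20-fold higher (log2 ratio 2.07, SE 0.14, adjusted p = 0.000727) and Mt1 2.74-fold higher (1.46, SE 0.11, adjusted p = 0.00117), each on 4 of 4 arrays. The other tested Mt2 probe was also called, at 1.08. Tdo2, which opens tryptophan breakdown, was 1.69-fold higher (0.76, SE 0.11, adjusted p = 0.0438), and Fga, the fibrinogen alpha chain, 1.65-fold higher (0.72, SE 0.10, adjusted p = 0.0438). Gstm2, a glutathione transferase, fell by 1.01 (SE 0.13, adjusted p = 0.0279). A further called Gstm2 probe stood at -1.11, and 3 uncalled ones at -1.12, -0.66 and 0.07. The chaperone gene Hsp90aa1 fell by 0.77 (SE 0.10, adjusted p = 0.0279), with its other probes at -0.65, -0.41, -0.33 and 0.11.

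A further 3 genes were called at 6 h on 1 probe that their other probes did not match. Ssr1, a translocon subunit gene, read 2.17 (SE 0.27, adjusted p = 0.0207) against -0.37, -0.24 and 0.15 on its other probes. Znrf2, a ubiquitin ligase gene, read 1.60 (SE 0.18, adjusted p = 0.0154) against 0.19 and -0.39. The ribosomal protein gene Rps14 read -1.01 (SE 0.11, adjusted p = 0.0111) against -0.06. The called probes of Mt1, Mt2, Tdo2, Ssr1 and Znrf2, 6 in all, were grouped by their correlation over the arrays. Of the 6, 5 stand within 48 of the 480 positions of a block. The Ssr1 probe and the Mt2 probe at 2.07 stand at the same position of different blocks. In all, 12 probes were called, 8 higher and 4 lower, and 748 had an unadjusted p under 0.05 where chance gives 587.45. The split turned without background correction (11 higher, 23 lower), without the dimmest 30% of probes (10 and 16) and with loess by blocks (9 and 12). Over 12 fits with 1 array left out, Mt1 and Mt2 kept their call in 12, Rps14 in 9, Znrf2 in 8, Ssr1 in 5, Gstm2 in 2, Hsp90aa1 in 1, and Tdo2 and Fga in 0. Leaving out 1 of the 6 h arrays left 2 to 3 called probes, and 0 were called when dye-swap pairs were averaged or 6 h was fitted alone.

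**Figure D2:**
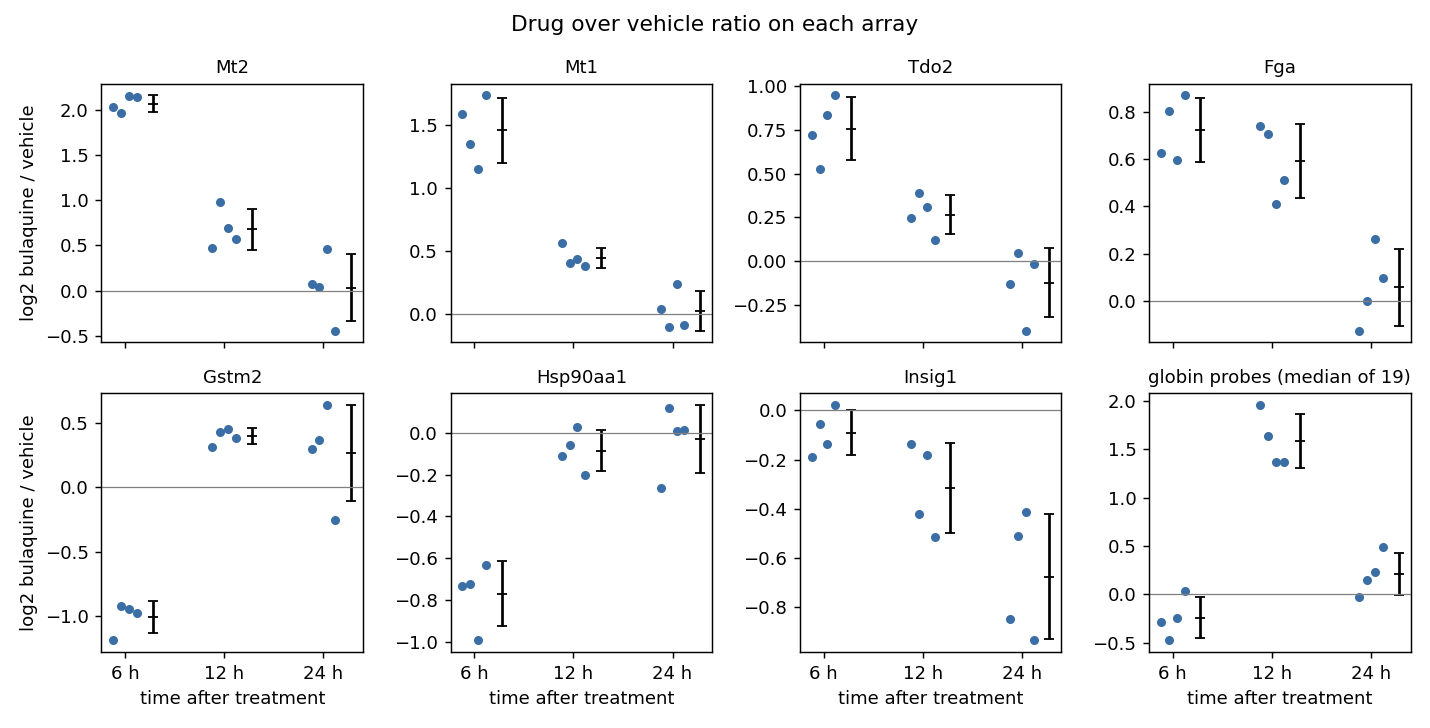
Log2 ratio of bulaquine over vehicle on each array (vertical axis, log2, dye effect removed) at 6 h, 12 h and 24 h (horizontal axis) for 7 named genes and for the median of 19 probes annotated to globin genes. Points are the 4 arrays, and bars the mean with its SD. Mt2 lies near 2.07 at 6 h and near 0.03 at 24 h, and the globin median peaks at 12 h.

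Interferon-stimulated genes fell together at 6 h. Of 12 measured members 11 lay below 0 with a median of -0.47 (camera adjusted p = 2.46e-07, and 0.00765 with an estimated correlation). No member passed over all probes, and 5 passed when adjusted over the list alone. Irf9 stood at -0.76, Igtp at -0.70 and Psmb8 at -0.46. Cytoskeleton genes fell as well, with 20 of 24 below 0 and a median of -0.15 (adjusted p = 3.75e-05, and 0.0165 with an estimated correlation). Adjusted over the list alone 5 members passed, and over all probes 0. The tubulins Tubb4b and Tubb2b stood at -0.54 and -0.70 and the actin Actg1 at -0.54.

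Genes of lipogenesis and lipoprotein metabolism fell at 6 h, with 19 of 22 below 0 and a median of -0.20 (adjusted p = 0.000799, and 0.022 with an estimated correlation). Adjusted over the list alone 4 passed, and over all probes 0. Scd1, the stearoyl-CoA desaturase, stood at -0.75 and the elongase Elovl5 at -0.44. Markers of macrophages and Kupffer cells, the liver's resident macrophages, lay below 0 for 5 of 6 members with a median of -0.39 (adjusted p = 0.0153), which was lost with an estimated correlation (adjusted p = 0.0908). Mpeg1 stood at -0.84, Csf1r at -0.67 and Lyz2 at -0.50, and 0 passed over the list alone. This fall stands beside that of the interferon-stimulated genes in the same arrays. Without array R1 or R2 of 6 h the macrophage list had an adjusted p of 0.131 and 0.0969. Of the 8 sign patterns of the 6 h arrays, 2 moved as many as 4 lists, the real one among them. The count of lists that moved at 6 h therefore does not exclude chance.

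**Figure D3:**
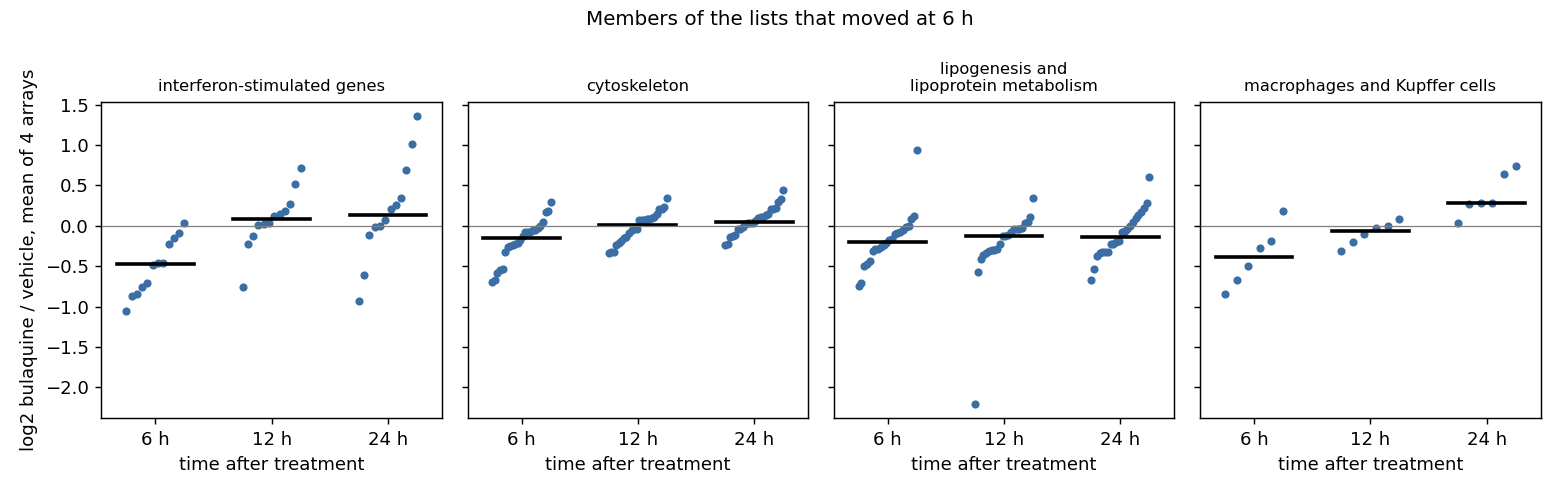
Log2 ratio of bulaquine over vehicle (vertical axis, mean of 4 arrays) of each measured member of the 4 lists that moved at 6 h, at 6 h, 12 h and 24 h (horizontal axis). Points are genes in order of their value and lines the medians. At 6 h the medians are -0.47, -0.15, -0.20 and -0.39.

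Lists for drug metabolism and stress did not pass camera at 6 h. Phase I enzymes had a median of -0.09 (7 measured, adjusted p = 0.151) and phase II enzymes and transporters one of 0.03 (12 measured, adjusted p = 0.907). Antioxidant and Nrf2 target genes split into 9 above and 10 below 0 (adjusted p = 0.492) although Mt1 and Mt2 are among them. Heat shock genes (adjusted p = 0.23), the unfolded protein response (0.907) and p53 and apoptosis genes (0.151) did not pass either. Acute phase proteins had 7 of 10 above 0 (adjusted p = 0.143), and heme and iron genes 13 of 19 below 0 (adjusted p = 0.151). The heat shock, acute phase, and heme and iron lists did pass fry's directional test (adjusted p = 0.0322 each). Among lists of liver metabolism, cholesterol synthesis came nearest, with 12 of 14 below 0 (adjusted p = 0.0821), followed by ribosomal proteins (0.182) and the proteasome (0.186). Glycolysis (0.992), the urea cycle (0.865), fatty acid oxidation (0.907), oxidative phosphorylation (0.907), clock genes (0.907), cell cycle genes (0.992), complement and coagulation (0.907) and cytokines (0.524) lay further off. The chemokine gene Cxcl1 read 2.31 at 6 h without passing (adjusted p = 0.18).

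At 12 h the arrays showed a rise of probes annotated to globin genes, the protein chains of hemoglobin. All 19 tested probes of this kind, 18 of which list several symbols so that no single gene is named, lay above 0, with a median log2 ratio of 1.63 (3.10-fold, SD over probes 0.52). Of these, 13 were called, 11 alpha and 2 beta. The 11 alpha probes all list the histone gene H3f3a beside Hba-a1 and Hba-a2, while the 2 beta probes list globin genes alone. The median per array ran from 1.37 to 1.96 at 12 h, and the medians over probes were -0.26 at 6 h and 0.19 at 24 h with 0 called. These probes were singled out after their values had been seen. The list of erythrocyte genes had 1 measured member, Car2, at 0.22 (adjusted p = 0.91).

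The named genes that rose at 12 h belong mostly to the same profile. Of 49 higher probes, 44 rose and fell together over the 12 arrays (median pairwise r of 0.91 across arrays). Of these, 13 were globin probes, 14 had 1 symbol and 17 had none. The group was formed by clustering the probes called higher on this same correlation, so a high r is built in. The groups of like profile at 6 h and 24 h were formed in the same way. Cetn2, a centriole protein gene, read 1.74 (SE 0.11, adjusted p = 0.000122), Phtf1 1.87 (SE 0.19, adjusted p = 0.00132), Larp7 1.46 (SE 0.13, adjusted p = 0.00095) and the mitochondrial aminotransferase gene Got2 1.11 (adjusted p = 0.0013). Tia1 (1.89), the nucleoporin gene Nup205 (1.65), Lrrc41 (1.49), Rhbdd3 (1.43), Add3 (1.37) and Fam131a (1.29) were called in this group too. The other probes of Tia1 and Add3 stood at -0.16 and -0.19, and the 31 members without globin annotation had a median dye effect of -0.26 against a mean of -0.29 in the globin members.

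Outside that group, Fga was also called higher at 12 h (0.59, adjusted p = 0.047). This 12 h call was not followed through the other fits, and that at 6 h held in 0 of 12 with 1 array left out. Serpina6, which encodes corticosteroid-binding globulin, was 1.99-fold lower (SE of the log2 ratio 0.14, adjusted p = 0.0135), Nkd2, a Wnt pathway inhibitor gene, fell by 0.89 (SE 0.15, adjusted p = 0.0412) and the clock repressor gene Ciart by 0.81 (SE 0.14, adjusted p = 0.0394). Gm1968 (2.48), Smad9 (2.33) and Nin (1.51) were higher at 12 h and again at 24 h. With 1 array left out, the 12 h calls of Rhbdd3, Nkd2 and Nin held in 2 of 12 fits each, that of Smad9 in 3 and that of Ciart in 1. In all 54 probes were called, 49 higher and 5 lower, and 1010 had an unadjusted p under 0.05. With dye-swap pairs averaged 9 were called, and with 12 h fitted alone or with normexp 0. By camera 0 lists passed, the nearest being acute phase proteins and lipogenesis (adjusted p = 0.056 each), both of which passed fry's directional test (adjusted p = 0.0358).

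At 24 h 55 of the called probes were higher and 1 lower. The share of lower ones depends on the processing, with 96 higher and 57 lower under normexp, 119 and 29 without the dimmest 30% of probes, and 171 and 22 without background correction. The largest rises with a name were Gm1968 (2.77, SE 0.30, adjusted p = 0.00371), the bone morphogenetic protein mediator Smad9 (2.74, SE 0.38, adjusted p = 0.0149), the histone acetyltransferase gene Hat1 (2.64, SE 0.44, adjusted p = 0.0392) and the centrosomal gene Nin (2.41, SE 0.26, adjusted p = 0.00371). Gm1968, Smad9 and Nin shared their profile with 9 called probes without a symbol. The other probes of Gm1968 and Hat1 stood at -0.09 and -0.16, and Hat1 kept its call in 2 of 12 fits with 1 array left out. Its log2 ratio was 0.33 without background correction and 0.26 with normexp at offset 50. Insig1, which restrains lipid and sterol synthesis, fell by 0.68 (SE 0.12, adjusted p = 0.0462) and kept its call in 0 of these fits.

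Smaller rises at 24 h included the neuronal adhesion gene Cntnap2 (1.56), Ascc3 (1.37), the nucleolin gene Ncl (1.10), Arhgef12 (1.02), the Raf inhibitor gene Pebp1 (1.02), Gdap1 (0.82) and Sema5a (0.82), of which Pebp1 kept its call in 1 of 12 fits with 1 array left out and the others in 8 or more. In the 17 alternatives that leave no array out, Pebp1 kept its call in 8, Gdap1 in 9 and the others in 10 to 14. Over these alternatives and the fits with 1 array left out, Gdap1 ran from 0.43 to 1.76 and Sema5a from 0.71 to 1.63. Naip3, of the NLR apoptosis inhibitor family, was called too (adjusted p = 0.00371), with its other probes at 0.96 and 0.22. Cth, which makes cysteine from cystathionine, read 0.66 (adjusted p = 0.015), and Irak1, a kinase of Toll-like receptor signalling, 0.74 (adjusted p = 0.015) with its other probes at -0.34 and 0.06. Those of Ascc3 stood at 0.36, 0.23 and -0.13, of Arhgef12 at 0.44 and of Sema5a at -0.29. In all 56 probes were called and 1535 had an unadjusted p under 0.05. Without array F1, F2 or R1 of 24 h 23, 15 and 22 were called, and 0 with dye-swap pairs averaged or 24 h fitted alone. By camera 0 lists passed at 24 h, where the list of macrophage markers had 6 of 6 members above 0 (median 0.28, adjusted p = 0.15).

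The time points differed in direct tests. Between 6 h and 12 h 47 probes differed, 45 of them higher at 12 h. Mt2 fell by 1.39 (SE 0.20, adjusted p = 0.0184) and Mt1 by 1.01 (SE 0.16, adjusted p = 0.031), while Cetn2 rose by 2.09 (SE 0.16, adjusted p = 0.000631). These calls held in 5, 2 and 12 of 12 fits with 1 array left out. Between 12 h and 24 h 21 differed, 8 higher and 13 lower at 24 h, among them Cetn2 (-1.56, kept in 12 of such fits) and Arhgef12 (1.16, kept in 3). That split was 67 and 32 without background correction, and 28 and 28 without the dimmest 30% of probes. Between 6 h and 24 h 22 differed, with Mt2 at -2.04, Mt1 at -1.43, the guanylate-binding protein gene Gbp5 at 1.54 and the cyclin gene Ccnd2 at 1.35. Without array F1, F2, R1 or R2 of 6 h, 1, 0, 0 and 0 probes differed from 6 h to 24 h. Over all 12 fits of this kind, Gbp5 and Ccnd2 kept that call in 1 each, Mt2 in 6 and Mt1 in 5. With dye-swap pairs averaged 0 probes differed in any of the 3 contrasts, while 772, 1048 and 1130 had an unadjusted p under 0.05 in the reported one. Over all time points 97 probes passed the joint test.

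Lists differed between time points for the interferon-stimulated genes, whose median difference was 0.62 from 6 h to 12 h (camera adjusted p = 6.05e-06, and 0.0153 with an estimated correlation) and 0.63 from 6 h to 24 h (adjusted p = 3.93e-05, and 0.0243). Cytoskeleton genes differed by 0.18 from 6 h to 12 h (adjusted p = 0.0158), which was lost with an estimated correlation (adjusted p = 0.131), and by 0.12 from 6 h to 24 h (adjusted p = 0.000707, and 0.0305). Macrophage markers differed by 0.55 from 6 h to 24 h (adjusted p = 0.000707, and 0.0305). Between 12 h and 24 h 0 lists differed by camera. The markers of stellate cells and of endothelial cells had medians of 0.04 and -0.07 at 6 h, and lists for neutrophils, lymphocytes, bile duct, pancreas, fat and muscle held too few measured members to test.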

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

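The tests of print position, of the annotated genes' other probes and of marks on the slide were chosen after the results were seen. So was the count of positions that members share. The tests of carry-over and of globin transcripts, and the sign patterns and splits of arrays, were written before their results. A test of the 12 h group by other probes of its genes was made under the deposited names, decided nothing and was replaced by the globin test after renaming.

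The 44 probes that rise together at 12 h form the first pattern. Carry-over of 1 DNA between spots of the same print step stays open. The 890 other probes at the members' positions, 0 of them called, lay 0.035 above the remaining uncalled probes (permutation p = 0.012), which argues against carry-over into most spots of a step. A median misses carry-over into a few spots, and the 44 members share 31 positions where random sets had a median of 42 and a lowest of 36. By position, 63.6% of members fall in a window of 48 of the 480 positions of a block, where random sets had a median of 20.5% and a highest of 36.4%. The files give no print order, so neighbouring steps of the print run stay open as the reason. Globin transcripts in the remaining 31 members are also in keeping with the values, their median dye effect lying 0.129 SD from the mean of the globin members (permutation p = 1e-04, the smallest it can give). Of the 13 globin members, 11 also list H3f3a, which this comparison cannot tell apart from globin. A candidate explanation is that named genes in this group, such as Cetn2 and Larp7, were read from spots that hold globin DNA; blood left in the tissue or an effect of the drug on it stays open and untested.

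The 12 probes with the largest rises at 24 h, among them Gm1968, Smad9 and Nin, form the second. Carry-over into most spots of the same print step is argued against. The 251 other probes at the members' positions, 0 of them called, lay 0.035 above the remaining uncalled probes (SD over random positions 0.024, permutation p = 0.085). Carry-over into a few spots stays open, since a median misses it. The 12 members stand at 11 positions, where random sets had a median of 12 and a lowest of 9 (permutation p = 0.13). Of the members 66.7% stand in 1 window of 48 positions (random median 33.3%, highest 75%, p = 0.0006 by permutation), and print steps stay open as above. Whether they measure transcripts of the annotated genes stays open, since the 1 other tested probe of these genes stood at -0.086. A drug effect on whatever these spots hold may remain and was not tested apart.

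The 37 probes near 0 at 6 h and 12 h that rose at 24 h form the third. In the fullest window stood 18.9% of members (random median 21.6%), and without a print order neighbouring print steps stay open. A mark on the slide is argued against, but only narrowly. The spots 1 and 24 places before and after the members had a median of 0.040 (SD 0.35), against 0.80 in the members. The rule asked for a median below 0.40 by more than the SD. The row length of 24 is assumed, since the files give no grid, so these spots may not all be neighbours. Transcripts of the annotated genes cannot be told apart from other content, because the 12 other probes of these genes had a median of 0.11 with an SD of 0.43. A response of the liver to the drug at 24 h may underlie this group and stays open.

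Single arrays stood apart in 5 of 43 sets of 4 values, where chance flags about 1 in 20. Array R1 of 12 h read 2.02 for Smad9 against 2.40 to 2.47 on the others, and array F2 of 12 h read 2.05 for Nin (others 1.29 to 1.39) and 1.90 for Larp7 (1.28 to 1.35). Array F1 of 24 h read 1.37 for Gm1968 (3.09 to 3.33) and 1.22 for Naip3 (0.89 to 0.94).

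Direct tests separated the time points for 47, 21 and 22 probes (6 h to 12 h, 12 h to 24 h and 6 h to 24 h). From 6 h to 12 h Gm1968 differed by 2.50, Tia1 by 2.24, Cetn2 by 2.09, Lrrc41 by 1.86, Phtf1 by 1.84, Mt2 by -1.39 and Mt1 by -1.01. From 12 h to 24 h Arhgef12 differed by 1.16, Naip3 by 1.01 and Cetn2 by -1.56. From 6 h to 24 h the differences were 2.79 for Gm1968, 1.95 for 9930111J21Rik2, 1.54 for Gbp5, 1.46 for Naaa, 1.35 for Ccnd2, -2.61 for Ssr1, -2.04 for Mt2, -1.77 for Znrf2 and -1.43 for Mt1. Many of these calls depend on single arrays. With 1 array left out, all those from 6 h to 24 h held in 1 of 12 fits except Mt2 (6) and Mt1 (5). From 6 h to 12 h Gm1968 held in 1, Mt1 in 2 and Mt2 in 5, and from 12 h to 24 h Naip3 in 1 and Arhgef12 in 3. The lists that differed were interferon-stimulated genes (0.62 and 0.63 against 12 h and 24 h), cytoskeleton (0.18 and 0.12) and macrophage markers (0.55 against 24 h). The cytoskeleton difference against 12 h was lost with an estimated correlation (adjusted p = 0.131).

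Sign patterns of the 4 arrays of a time point number 8, too few for a share under 0.05. The real pattern called 12, 54 and 56 probes at 6 h, 12 h and 24 h and the highest of the other patterns 0, 1 and 0, so 1 of 8 was as large each time. With arrays taken as independent, 1 of 35 splits of 8 arrays reached 47, 21 and 22 probes for the differences. The highest other split called 1, 0 and 0. That is the smallest share these splits can give. Many splits do not keep 2 arrays of each dye orientation per group and so estimate the difference less precisely. The share therefore does not exclude chance. If F and R arrays of 1 number share RNA, the arrays split are not independent either. Averaged dye-swap pairs called 0 in all 3 differences and the label as a fixed replicate block 19, 0 and 2. For the joint test 3 of 100 sign patterns, the real one among them, reached 97 probes. Both others called 2028 and aligned all 12 arrays with the dye. In these 2 the time point effects cannot be told apart from the dye effect, so a large count was fixed in advance. The highest pattern with 9 or fewer arrays along the dye called 28. Patterns differ in how evenly they spread over the dyes, so the share of 3 of 100 does not by itself exclude chance. For gene lists 2 of 8 patterns, the real one among them, gave as many lists as the 4 of 6 h (highest other 4). All 8 of 8 reached the 0 lists of 12 h (highest other 2) and of 24 h (highest other 0).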

How the results depend on the processing

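Directions of called genes held, and calls and sizes often did not. Over alternatives that leave no array out, 611 of 1001 values of called genes stayed called and 390 lost the call. With an array left out 383 of 708 stayed, and 0 reversed in either. Reversals were unlikely from the start, so their absence is weak support. All probes called at a time point had 1 sign on all 4 arrays, and the alternatives reuse the same arrays. The 611 include 59 values each from plain subtraction and from Aquantile, which could not differ from the reported ones. Of uncalled named genes 25 values passed and 8 moved, and with an array left out 1 passed and 5 moved. The cause was not tested unless stated. Under normexp with offset 50 the log2 ratio fell from 2.64 to 0.26 for Hat1 at 24 h, from 2.17 to 0.59 for Ssr1 at 6 h, and at 12 h from 1.51 to 0.22 for Nin, 1.65 to 0.41 for Nup205 and 1.46 to 0.45 for Larp7, while Mt2 at 6 h ran from 1.99 to 2.17 over all alternatives. Mt2 at 6 h lost its call with averaged pairs and with 6 h fitted alone. Low signal over background limits the dim probes, and 11291 probes were missing on 1 or more arrays. The planned print-tip loess could not be run because the files give no grid, and keeping copies of a probe apart gave no value because none is marked; plain subtraction and Aquantile leave the reported values as they are. Chosen after seeing the data were normexp with offset 50, the 2 wider probe sets, loess by blocks of 480 and names as deposited.

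Counts follow the order 6 h, 12 h and 24 h, then the differences 6 h to 12 h, 12 h to 24 h and 6 h to 24 h, then any time, against 12, 54, 56, 47, 21, 22 and 97 as reported. No background correction gave 34, 81, 193, 77, 99, 83 and 224. Normexp gave 11, 0, 153, 6, 0, 8 and 15 with offset 0, and 11, 0, 151, 6, 0, 8 and 14 with offset 50. On all probes it gave 11, 0, 84, 6, 0, 5 and 13. Loess by blocks of 480 gave 21 at 6 h, and median centring 40 from 12 h to 24 h. Without the dimmest 30% the counts were 26, 67, 148, 57, 56, 50 and 148. Without the dye effect they were 6, 32, 14, 10, 0, 2 and 43. Averaged pairs, with fewer values, gave 0, 9, 0, 0, 0, 0 and 0, and each time point fitted alone gave 0, 0 and 0. Probes on at least 3 of 4 arrays gave 6, 44, 38, 32, 8, 2 and 68, and corrected intensity plus 50 on all probes gave 2, 39, 24, 15, 0, 0 and 41. Trend with robust eBayes gave 12 from 6 h to 24 h. An adjusted p under 0.01 left 2 at 6 h and 19 at 24 h.

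The values leave open whether arrays of 1 number share RNA. Arrays of 1 label share the dye, and removing its effect makes their correlation negative, so arrays of 1 orientation at different time points were set against each other. Those of 1 number had a median r of -0.15 and those of other numbers -0.13. Within a time point, F and R arrays of 1 number had a median r of 0.11 and those of other numbers 0.13, for drug over vehicle with the dye effect removed. The consensus correlation within blocks of F and R arrays of 1 number was 0.16, but on log2(Cy5/Cy3) not turned by dye orientation. Shared RNA would enter those ratios with opposite signs, so a positive value does not speak for it. A random replicate block with this correlation gave 20, 69, 132, 53, 61, 44 and 137 probes. A positive correlation there narrows the error of the drug effect, so these counts are no check on shared RNA. The array label as a fixed replicate block gave 19, 0 and 2 for the differences.

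Lists moved at 6 h, 12 h and 24 h were 4, 0 and 0 as reported. They were 6, 4 and 0 without background correction, 6, 7 and 0 with normexp at either offset and 8, 7 and 0 on all probes. Loess by blocks gave 4, 3 and 0, no dye effect 6, 1 and 0, averaged pairs 5, 0 and 1, and trend, the authors' log2 value table and the mean over probes 2 each at 12 h. Fry gave 7, 2 and 0 by direction and 15, 9 and 10 in either direction. Names by the deposited spot label gave 0 lists at 6 h.

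With 1 array left out, 2 to 9 probes were called at 6 h, 37 to 59 at 12 h and 15 to 44 at 24 h, and the differences gave 21 to 43, 3 to 16 and 0 to 19, and any time 55 to 67. Lists ran from 3 to 6 at 6 h, 0 to 3 at 12 h and 0 to 0 at 24 h. At 6 h, 3, 2, 2 and 3 probes were called without F1, F2, R1 and R2 of 6 h, and 5 without R1 or R2 of 12 h or F2 of 24 h. At 24 h, 23, 15, 22 and 37 were called without F1, F2, R1 and R2 of 24 h and 36 without R1 of 12 h. Leaving out F1, F2, R1 and R2 of 6 h, then of 12 h, then of 24 h gave 21, 30, 22, 31, 30, 32, 30, 31, 41, 32, 43 and 43 probes for 6 h to 12 h. The same order gave 14, 8, 10, 15, 4, 9, 8, 12, 12, 3, 16 and 12 for 12 h to 24 h, 1, 0, 0, 0, 7, 15, 0, 2, 19, 0, 8 and 8 for 6 h to 24 h and 59, 58, 55, 55, 56, 61, 56, 59, 63, 60, 64 and 67 at any time.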

Other observations

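Gbp5, an interferon-inducible GTPase gene, read -0.84 at 6 h, -0.06 at 12 h and 0.71 at 24 h, while the listed interferon-stimulated gene Gbp2 read -0.84, -0.75 and 1.36 and passed at 0 of the 3 time points and in 0 differences between them. Ccnd2 read -0.85, 0.21 and 0.50. The 6 h to 24 h calls of Gbp5 and Ccnd2 held in 1 of 12 fits with 1 array left out. Among fatty acid oxidation genes Vnn1 read 1.43 at 24 h (adjusted p = 0.097), and among heme genes Alad read -0.72 (adjusted p = 0.12).

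Called probes of Mt1, Mt2, Tdo2, Ssr1 and Znrf2 at 6 h, 6 in all, followed 1 profile over the 12 arrays (median pairwise r of 0.87). The group was formed by clustering on this correlation, so a high r is built in. Of these 6 probes, 83.3% stand within 48 of the 480 positions of a block (random median 33.3%, highest random 83.3%, permutation p = 0.0027). The Ssr1 probe and the Mt2 probe at 2.07 both stand at position 45, in blocks 22 and 21. The 6 members share 5 positions (random median 6, permutation p = 0.03), and carry-over between spots stays open for this group. The 5 other probes of 2 of their genes had a median of -0.24 at 6 h. Across 3118 pairs of tested probes of 1 gene, under the renumbered names, the correlation was 0.21 for mean log2 intensity, 0.32 for the dye effect and 0.09, 0.05 and 0.07 for the log2 ratio at 6 h, 12 h and 24 h. Genes are not independent replicates, so no p is given.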
